A study of Homo sapiens with 9 samples.

How the data were processed

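The data are 9 arrays from 3 xenograft experiments, each with 1 array per arm (control, AraC, AraC with venetoclax). Per the labels' protocols, mice were conditioned with busulfan at 20 mg/kg, MOLM-14 cells were injected, and treatment began after 10 days. Sorted viable human cells gave RNA, of which 100 ng was reverse transcribed and labelled as biotinylated cRNA with the GeneChip WT PLUS kit for an Affymetrix array. One label speaks of RNA sequencing; the type of the series, the label protocol and the values are those of an array. How many mice gave the RNA of 1 array, and what control mice received in place of the drugs, is not given in the sources used here.

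The authors deposited 1 table of log2 expression values, made by RMA per the submitters' processing notes, with no version given. RMA corrects the background, normalizes between arrays and summarises the probes of a probe set. Sorted values differed between arrays by at most 0.274, which fits arrays that share nearly 1 distribution. Values ran from 1.36 to 14.0 and array medians from 4.47 to 4.52, and no centring of genes was seen. Background settings, batch correction and probe filters are not given in the sources used here. No detection calls were used, so signal over background is not known per probe set. The 9 columns were matched to samples by name, and no pair of arrays held identical values; correlations between arrays lay between 0.975 and 0.99.

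Of 53617 probe sets, 16098 had exactly 1 gene symbol in the platform annotation, 0 had several and 37519 were unnamed here. The symbols of all 16098 were found in the RefSeq gene table. For each of the 14884 genes the probe set with the highest mean over all 9 arrays was used. Of these genes 11916 are protein-coding and 1072 are microRNA genes. CD33, PTPRC, CDKN1A and MDM2 are among those unnamed here and were not analysed.

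Tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend; two-sided; Benjamini-Hochberg over all genes; threshold 0.05). All 9 arrays entered 1 fit with arm and experiment as terms, which leaves 4 residual degrees of freedom. The experiment was a block because the series text and the labels lay the study out as complete repeats, each with its own batch label. The cells were labelled IDH R132H, wild type or without IDH status. The fit without the block is an alternative. This pairing comes from the labels. As a check, deviations of arrays from their arm means correlated between 0.0593 and 0.337 within an experiment (median 0.212, over 0.1 in 8 of 9 pairs) and between -0.267 and 0.0912 across experiments, and all 9 arrays were closest to an array of their own experiment. Experiments are separate xenograft rounds and enter as a block. P-values between arms therefore measure how differences between arms vary from round to round, with array noise included. P-values between experiments rest on that same residual spread, so they do not measure the spread between repeated rounds.

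Before the data were examined, 39 gene lists were fixed, of which 35 had at least 5 measured members and were tested with limma's camera (preset inter-gene correlation 0.01, Benjamini-Hochberg over the lists of a comparison), and again with an estimated correlation and with fry. They cover respiration and metabolism (complexes II to V, mitochondrial ribosome, TCA cycle, fatty acid oxidation and synthesis, glycolysis, hypoxia, cholesterol synthesis, NRF2), cell death and drug response (p53 targets, BCL2 family, cytarabine transport and metabolism, DNA damage), growth (mitotic genes, DNA replication, MYC targets, cytosolic ribosomal proteins), stress and inflammation (ATF4 response, unfolded protein response, interferon, MHC class I, NF-kB, lysosome and autophagy, heat shock, immediate early genes), leukemia and myeloid identity (monocyte, granulocyte, LSC17, KMT2A fusion targets, surface and sort markers) and other cell types (erythroid, megakaryocyte and platelet, T and NK, B and plasma, stromal and endothelial). Respiratory complex I, mitochondrially encoded genes and replication-dependent histones had 0 named members and MHC class II had 1, so these 4 were not tested. With an estimated correlation no list passed in any comparison of arms or experiments, so a call lost under it says little about that list. For each list the members were also adjusted over the list alone.

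Named genes follow a rule fixed before the data were examined. Where fewer than 3 genes passed in a direction, the 5 genes with the smallest p that moved the same way in all 3 experiments are given as values, and MIR, antisense, LINC and similar symbols are passed over. Up to 4 members with the smallest p may be named per list, and members of the BCL2 family and of cytarabine metabolism are always allowed. Gene differences are log2 differences with limma's standard error, and an experiment's value is the difference between its 2 arrays.

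The scripts were tested on simulated data with the real means and spread, in which 200 of 14884 genes were changed, in 10 data sets per comparison. For the combination against control, 68.7% of 1.5-fold changes and 99.6% of 2-fold changes were recovered; for AraC against control 68.8% and 99.7%; for the combination against AraC 72.5% and 99.4%. Unchanged genes made up 12.8 of 191.5, 14.7 of 193.5 and 13.6 of 194.8 calls on average, somewhat more than the nominal share. With fewer changed genes the Benjamini-Hochberg cutoff is stricter, so the recovered shares do not carry over to data with few changes. Lists shifted by 0.2 were recovered in 5, 5 and 4.9 of 5 cases on average. The simulated noise was independent between genes, while the correlation estimated for mitochondrial ribosome genes was 0.358. The recovery of lists therefore does not carry over to lists whose genes move together. Unchanged arms against the real control arrays were simulated 100 times for the correlation of changes. Alternatives left out the block, the third arm, the trend, dim genes, or each replicate and array in turn, or used robust moderation, array weights, the mean of a gene's probe sets, median or quantile scaling, and a 1.5-fold threshold. Added after the data were seen were protein-coding genes only, all probe sets, changes from different experiments, and the comparison of experiments with its alternatives. Figures were drawn with matplotlib 3.10.9.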

Results

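Gene expression was measured in MOLM-14 cells, a human acute myeloid leukemia line with a KMT2A fusion, that had been grown as xenografts in the bone marrow of mice. Mice received no AraC or venetoclax (control), AraC alone or AraC with venetoclax. AraC (cytarabine) is a nucleoside analogue that blocks DNA synthesis, and venetoclax inhibits the anti-apoptotic protein BCL2. AraC was given for 5 days at 30 mg/kg and venetoclax for 7 days at 100 mg/kg, and human cells that expressed CD45 and CD33 and did not bind annexin V were then sorted. The whole course was run in 3 xenograft experiments, and each gave 1 array per arm, so there were 9 arrays and 3 per arm. Experiment 1 used cells labelled IDH R132H, experiment 2 cells labelled wild type, and experiment 3 carried no IDH status. Array medians lay between 4.47 and 4.52 on the log2 scale. The number of arrays limits the precision: the 95% interval of a difference had a median half-width of 0.27 on the log2 scale, or 1.21-fold.

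**Figure D1:**
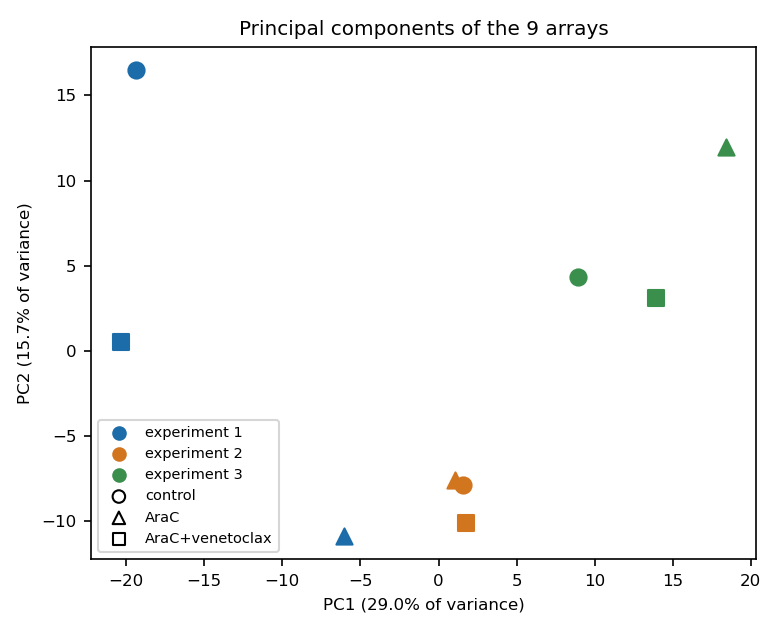
Principal components of the 9 arrays over all named genes, with PC1 (29.0% of the variance) on the horizontal axis and PC2 (15.7%) on the vertical axis. Colours give the xenograft experiment and symbols the arm; the 3 arrays of experiment 3 have the highest PC1 values and the 3 arrays of experiment 1 the lowest, and the arms do not separate.

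The first comparison asked what AraC with venetoclax left behind in the surviving cells relative to control. RGS1, a regulator of G protein signalling in leukocytes, had a mean log2 value of 7.58 in control cells and 8.26 after the combination, a difference of 0.67 ± 0.11 (SE, n = 3 arrays per arm) or 1.59-fold, and was higher in 3 of 3 experiments. CD86, a costimulatory protein of monocytes and dendritic cells, differed by 0.49 ± 0.10, CPED1 by 0.65 ± 0.13, EHD3 by 0.58 ± 0.13 and TMEM161A by 0.40 ± 0.09. On the lower side, SCD, the desaturase that makes monounsaturated fatty acids, differed by -0.51 ± 0.10 (7.66 in control and 7.16 after the combination). KCNRG differed by -0.53 ± 0.10, BNIP2 by -0.48 ± 0.10, N4BP3 by -0.47 ± 0.11 and the cytokine receptor CRLF2 by -0.49 ± 0.11. These genes, like those that lead the other comparisons, moved the same way in 3 of 3 experiments because the rule for naming them required it. None of these genes passed the test over all genes (adjusted p 0.618 for RGS1 and 0.943 for CD86 and SCD). SCD passed when adjusted over the list alone among 11 fatty acid synthesis genes (adjusted p = 0.00581), of which 7 were higher, as did CD86 among 22 monocyte differentiation genes (adjusted p = 0.0131). These were the 2 passes over 35 lists, each adjusted by itself, where a few come by chance. For 14884 genes limma called 0 at an adjusted p under 0.05, with 734 at an unadjusted p under 0.05 where chance gives 744, and the moderated F test over the 3 arms also called 0, with 651 unadjusted. The lowest adjusted p was 0.0839, for the microRNA locus MIR601 (1.07 ± 0.13), which was chosen for mention after its values were seen and passed under median scaling (adjusted p = 0.046). The interval excluded a 2-fold change for 99.4% of genes and a 1.5-fold change for 90.6%.

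MYC targets, genes of ribosome and nucleotide synthesis, were the 1 list of 35 that passed in this comparison. Their median difference was 0.09, with 22 of 28 members higher (camera adjusted p = 0.0445), and this call was lost with a term for the gene-to-gene correlation (adjusted p = 0.808 with an estimated correlation). Of the members, 0 passed over all genes and 0 adjusted over the list alone. The spermidine synthase SRM differed by 0.44 ± 0.15, the exosome subunit EXOSC5 by 0.36 ± 0.16 and MYC itself by 0.34 ± 0.15. The list's median was 0.17 in experiment 1, 0.01 in experiment 2 and 0.06 in experiment 3 (mean 0.08 ± 0.08 SD). Over 24 alternative settings the adjusted p ran from 0.0145 to 0.808, with a value of 0.159 without the experiment as a block. It was also lost without replicate 1 (adjusted p = 0.766) or 2 (0.0759), and without single arrays: control replicate 1 (0.718), AraC+venetoclax replicate 1 (0.389) or 2 (0.153), or AraC replicate 2 (0.0682).

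Cholesterol synthesis genes had the second smallest p, with a median of -0.13 and 11 of 17 members lower (-0.20, -0.13 and -0.06 in the 3 experiments; adjusted p = 0.067). The adjusted p ran from 0.0378 to 0.808 over 24 settings and was under 0.05 in 3: protein-coding genes only (0.0378), only the 6 arrays compared (0.0487) and without AraC replicate 1 (0.0408), none of which held with an estimated correlation (adjusted p = 0.808 with an estimated correlation and all arrays). Squalene epoxidase SQLE differed by -0.48 ± 0.19, INSIG1, which retains the sterol sensor in the endoplasmic reticulum, by -0.42 ± 0.12 and mevalonate kinase MVK by -0.31 ± 0.13, while PMVK, the next enzyme of the pathway, differed by 0.24 ± 0.11. For subunits of respiratory complexes II to V, 13 of 15 were higher with a median of 0.09 (adjusted p = 0.121), led by COX6A1 at 0.20 ± 0.07. Their median was 0.15, -0.01 and 0.07 in the 3 experiments, 0.01 without control replicate 1 and 0.14 without replicate 2. The list was called with only the 6 arrays compared (adjusted p = 0.0487), without AraC replicate 1 (0.0408) and without control replicate 2 (0.0197). None of these calls held with an estimated correlation in the same fit (lowest adjusted p = 0.741 with an estimated correlation). No list passed under that setting in any comparison with all arrays, so such a loss says little about a single list. The list of surface and sort markers had a median of -0.09 (adjusted p = 0.336), which was 0.02 without replicate 1 or AraC+venetoclax replicate 1. CD33 and PTPRC, the gene of CD45, were not analysed, so the list does not cover the proteins CD45 and CD33 used for sorting. In these 3 lists, 0 members passed over all genes and 0 adjusted over the list alone. The type I interferon list had a median of 0.05 with 17 of 29 members higher, and its leading members differed between experiments. IFIT2 differed by -0.98 in experiment 1, 1.22 in experiment 2 and 2.63 in experiment 3, and IFIT3 by -0.34, 0.77 and 1.87; no test compared the experiments.

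**Figure D2:**
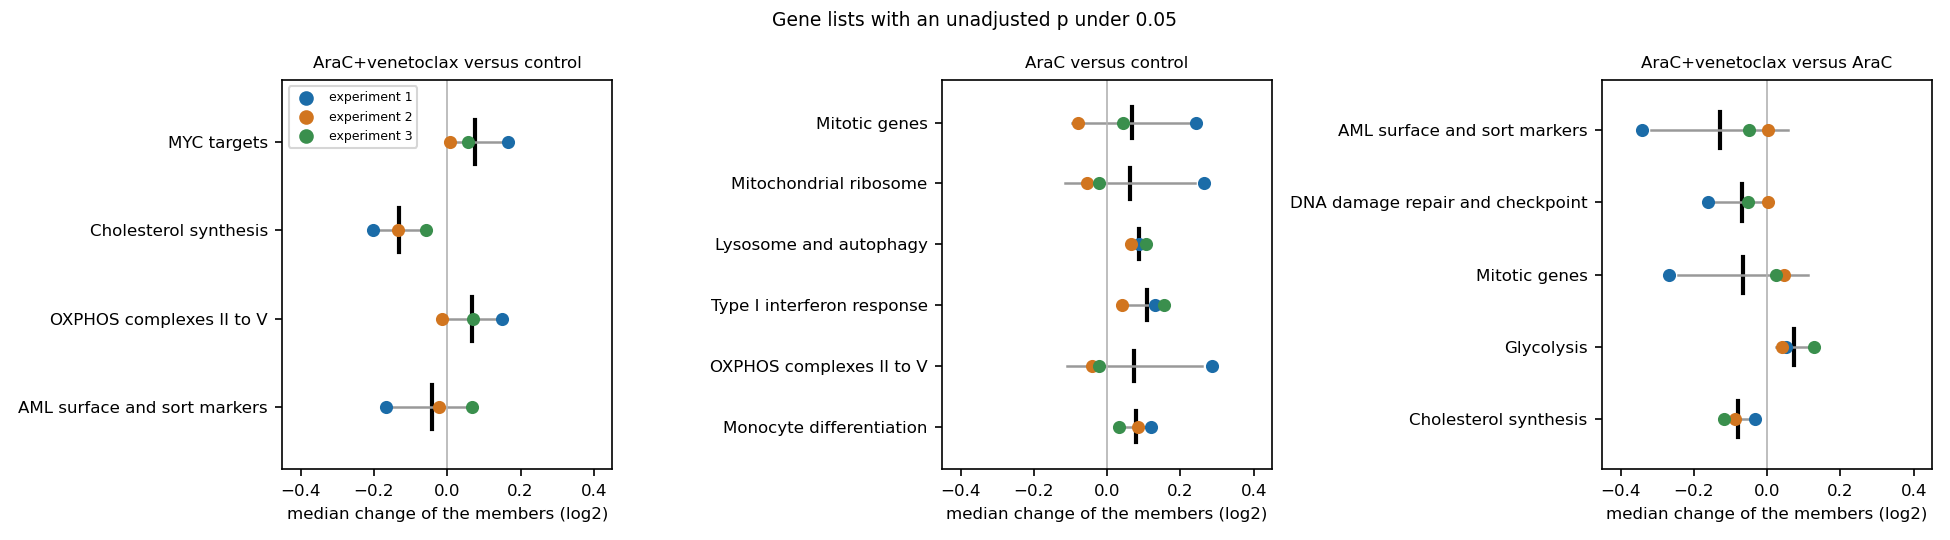
Median log2 difference of the members of each gene list with an unadjusted p under 0.05, in 1 panel per comparison, where points are the 3 experiments, black ticks their mean and grey lines 1 SD to either side. For AraC versus control, the mitochondrial ribosome median is 0.27 in experiment 1 and -0.06 and -0.02 in experiments 2 and 3.

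The second comparison asked what AraC alone left behind. RGS1 again had the smallest p among protein-coding genes named here (0.54 ± 0.11 above control, 3 of 3 experiments), followed by DUSP19 (0.64 ± 0.14), FBXW4 (0.61 ± 0.13) and the zinc finger gene ZNF763 (0.90 ± 0.20), and the pseudogene CEP170P1 differed by 0.61 ± 0.12. On the lower side stood KCNRG (-0.44 ± 0.10), N4BP3 (-0.45 ± 0.11), the receptor NOTCH3 (-0.48 ± 0.12), the divergent transcript ARGLU1-DT (-0.65 ± 0.16, and -0.40 without replicate 3 or -0.42 without control replicate 3) and the pseudogene SPRNP1 (-0.56 ± 0.11). CD86 differed by 0.42 ± 0.10 and passed when adjusted over the list alone among monocyte genes (adjusted p = 0.0409). The chemokine receptor CXCR2, at 0.58 ± 0.13, did so among 17 granulocyte markers (adjusted p = 0.0207). Neither passed over all genes (adjusted p = 0.999), and they were the 2 passes over 35 lists, where a few come by chance. Of 14884 genes limma called 0, with 593 at an unadjusted p under 0.05, and the interval excluded a 2-fold change for 99.5% of genes. The lowest adjusted p belonged to 2 microRNA loci, which were chosen for mention after their values were seen. MIR3143 differed by -0.79 ± 0.09 (adjusted p = 0.0565) and MIR32 by 1.35 ± 0.17 (adjusted p = 0.0634), and both passed under median scaling (adjusted p = 0.0483 for each) and under array weights (adjusted p = 0.024 for each).

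Of the 35 lists camera called 0 after AraC alone, with 6 at an unadjusted p under 0.05; an estimated correlation called 0 (1 unadjusted), and fry 0 (3 unadjusted). Mitotic genes had a median of 0.10 with 23 of 31 members higher (adjusted p = 0.0521), led by CDK1 at 0.35 ± 0.17 (-0.08 in experiment 2) and CENPA at 0.26 ± 0.14. Mitochondrial ribosome genes had a median of 0.08 with 54 of 70 higher (adjusted p = 0.0521), and all 15 measured subunits of complexes II to V were higher (median 0.06, adjusted p = 0.0782). All 3 medians lay at 0.24 or above in experiment 1 and between -0.08 and 0.04 in experiments 2 and 3, and without replicate 1 they were -0.01, -0.03 and -0.02. With 1 replicate or array left out, mitochondrial ribosome genes were called in 6 of 12 cases (median up to 0.12, lowest adjusted p 6.4e-05 without AraC replicate 3), mitotic genes in 5 (up to 0.19, lowest 0.000433 without AraC replicate 2) and complexes II to V in 3 (up to 0.12, lowest 0.0105 without AraC replicate 3). None of these calls held with an estimated correlation in the same fit (lowest adjusted p = 0.748 with an estimated correlation), a setting under which no list passed in any comparison. Interferon genes had a median of 0.10 (23 of 29 higher, adjusted p = 0.0603), lysosome and autophagy genes 0.07 (17 of 21 higher, adjusted p = 0.0579) and monocyte genes 0.06 (15 of 22 higher, adjusted p = 0.29), each above 0 in 3 of 3 experiments. Leaving out 1 replicate or array moved these medians to between 0.04 (without control replicate 3) and 0.14 (without replicate 2) for interferon, 0.03 (without replicate 3) and 0.13 (without AraC replicate 2) for lysosome and autophagy, and 0.02 (without AraC replicate 1) and 0.12 (without replicate 3) for monocyte genes. Among lysosome and autophagy genes GABARAPL1 differed by 0.47 ± 0.13. In these 6 lists 0 members passed over all genes, and adjusted over the list alone CD86 did. Mitochondrial ribosome genes, mitotic genes, complexes II to V and, without control replicate 2, interferon genes (adjusted p = 0.0437) made up the calls with 1 left out. None of these calls held with an estimated correlation (adjusted p = 0.798 for interferon genes in the same fit). Their number was 2 without replicate 2 and 3 without replicate 3, and single arrays left out gave 4 (control replicate 2), 3 (AraC replicate 3), 2 (AraC replicate 2) or 1 (control replicate 3).

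**Figure D3:**
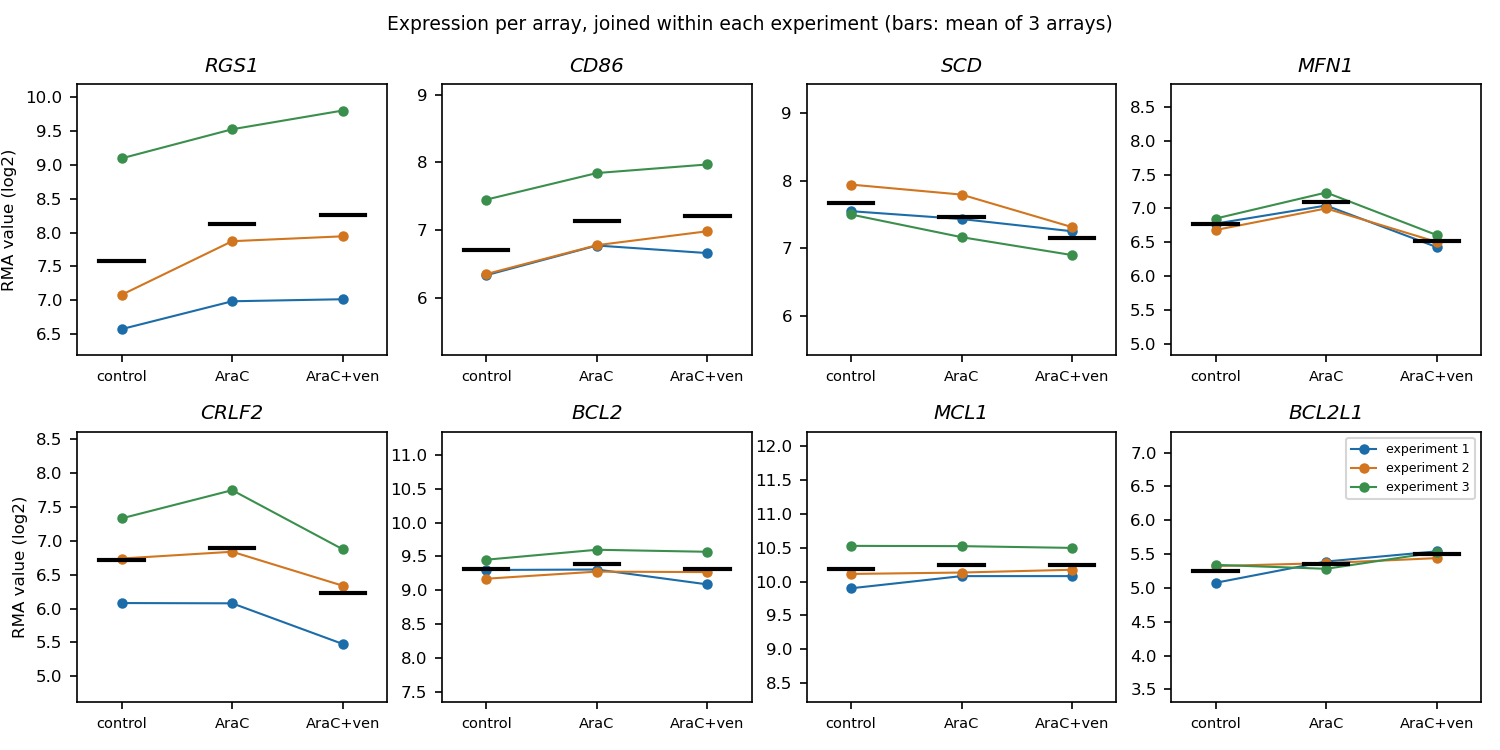
RMA expression (log2, vertical axis) of 8 genes on each array, by arm, with lines that join the 3 arrays of an experiment, black bars for the mean of an arm and 4 log2 units in every panel. RGS1 is higher after AraC and after the combination than in control in each experiment, and lies about 6.14-fold higher in experiment 3 than in experiment 1.

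The third comparison set the combination against AraC alone, and so isolates the addition of venetoclax. MFN1, which drives fusion of mitochondria, was at 7.09 after AraC and 6.51 after the combination (-0.58 ± 0.09, 3 of 3 experiments), and CRLF2 differed by -0.66 ± 0.11, ANKRD66 by -0.61 ± 0.12, the lipid-presenting molecule CD1A by -0.64 ± 0.13 and GRAPL by -0.56 ± 0.12. Higher values were measured for the kinase MAP2K6 (0.57 ± 0.12), the heat shock factor HSF1 (0.49 ± 0.11), HES5 (0.56 ± 0.12), ROPN1 (0.78 ± 0.18) and TIGAR (0.44 ± 0.10), a p53 target that lowers glycolytic flux. TIGAR passed when adjusted over the list alone among 18 p53 targets (adjusted p = 0.0238), a list in which 14 members were lower and 4 higher (median -0.08, below 0 in 3 of 3 experiments, camera adjusted p = 0.832). DDIT4, an inhibitor of mTORC1, did so among 14 hypoxia genes (0.41 ± 0.11, adjusted p = 0.0454), of which 7 were higher (median 0.01). TIGAR and DDIT4 were the 2 passes over 35 lists, where a few come by chance. Over all 14884 genes limma called 0, with 739 at an unadjusted p under 0.05, a lowest adjusted p of 0.176 and values of 0.398 for MFN1 and 0.44 for CRLF2. A 2-fold change was excluded for 99.5% of genes.

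Of the 35 lists camera called 0 for the addition of venetoclax, with 5 at an unadjusted p under 0.05; an estimated correlation called 0 (0 unadjusted), and fry 0 (3 unadjusted). Surface and sort markers, again without CD33 and PTPRC, had a median of -0.10 with 13 of 15 lower (adjusted p = 0.0907). They were led by CD70 at -0.30 ± 0.11 and CXCR4 at -0.21 ± 0.12. The median was -0.34 in experiment 1 and 0.00 and -0.05 in experiments 2 and 3. Leaving out 1 replicate or array gave -0.04 (without AraC replicate 1) to -0.16 (without replicate 2), with an adjusted p under 0.05 in 6 of 12 cases. None of the 18 list calls made in this comparison with 1 left out held with an estimated correlation (lowest adjusted p = 0.805 with an estimated correlation). That setting passed no list in any comparison, so the loss says little about a single list. DNA damage genes had a median of -0.06 (16 of 24 lower, adjusted p = 0.17; ATR -0.27 ± 0.11), and from -0.04 (without AraC+venetoclax replicate 1) to -0.11 (without AraC+venetoclax replicate 2) with 1 left out, called without AraC replicate 2 (adjusted p = 0.0474). Mitotic genes had a median of -0.09 (21 of 31 lower, adjusted p = 0.17), which was 0.03 without replicate 1 or AraC replicate 1, -0.01 without AraC+venetoclax replicate 1 and -0.12 without AraC replicate 2. The adjusted p of mitotic genes was under 0.05 in 5 of 12 cases with 1 replicate or array left out, with a lowest value of 0.00262 without AraC replicate 2. All 9 glycolysis genes measured were higher, with a median of 0.08 (adjusted p = 0.189). Cholesterol synthesis genes had a median of -0.06 (11 of 17 lower, adjusted p = 0.313), led by MSMO1 at -0.53 ± 0.16 and SQLE at -0.54 ± 0.19. The cholesterol median was -0.01 without AraC replicate 3. In these 5 lists 0 members passed over all genes and 0 adjusted over the list alone. The number of lists called was 2 without replicate 2 and 4 without replicate 3, and single arrays left out gave 4 (AraC replicate 3), 3 (AraC replicate 2 or AraC+venetoclax replicate 3) or 1 (control or AraC replicate 1). Beside surface markers, mitotic and DNA damage genes, these were immediate early genes without replicate 3 (median 0.16, adjusted p = 0.0069), AraC replicate 3 or AraC+venetoclax replicate 3, and mitochondrial ribosome genes. The mitochondrial ribosome median was -0.08 without replicate 3 or AraC replicate 3 and 0.07 without AraC replicate 1 (adjusted p = 0.0228).

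BCL2, the target of venetoclax, differed from control by 0.00 ± 0.09 after the combination and 0.09 ± 0.09 after AraC. MCL1, an anti-apoptotic relative that venetoclax does not bind, differed by 0.07 ± 0.07 in both comparisons. BCL2L1, which encodes BCL-XL, differed by 0.26 ± 0.12 after the combination and 0.10 ± 0.12 after AraC. For the addition of venetoclax to AraC the differences were -0.09 ± 0.09 for BCL2, 0.01 ± 0.07 for MCL1 (below 0 with quantile normalization) and 0.16 ± 0.12 for BCL2L1. With 1 replicate or array left out, BCL2L1 ran from 0.15 (without control replicate 1) to 0.33 (without replicate 2) after the combination and from 0.09 (without AraC replicate 3) to 0.21 for added venetoclax. In the same way MCL1 ran from 0.02 to 0.12 after the combination and 0.01 to 0.11 after AraC, lowest without control replicate 1 and without replicate 1, and BCL2 from 0.04 (without control replicate 3) to 0.16 (without control replicate 1) after AraC. The effector BAK1 differed by 0.31 ± 0.11 and the BH3-only gene BCL2L11 by -0.31 ± 0.14 after the combination (0.08 in experiment 1, and -0.58 and -0.43 in experiments 2 and 3), and 0 of 15 family members passed over all genes or adjusted over the list alone in any comparison. Among 7 genes of cytarabine transport and metabolism, DCK, the kinase that activates cytarabine, differed from control by 0.34 ± 0.13 after the combination and 0.30 ± 0.13 after AraC, and the deaminase DCTD by 0.39 ± 0.16 and 0.24 ± 0.16 (-0.01 and -0.24 in experiment 2); neither passed in either count. The deaminase CDA differed by -0.02 ± 0.12 after the combination and SAMHD1, which hydrolyses the active nucleotide, by -0.06 ± 0.12.

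No list of markers of other cell types passed in any comparison. After the combination the medians were -0.09 for erythroid, -0.05 for megakaryocyte and platelet, -0.00 for T and NK cell, -0.00 for B and plasma cell and 0.05 for stromal and endothelial markers (lowest adjusted p 0.384). Heat shock and immediate early genes, which respond to handling, had medians of -0.01 and 0.07. Immediate early genes were called without replicate 3 (median 0.13, adjusted p = 0.0246) and without AraC+venetoclax replicate 3 (median 0.17, adjusted p = 0.00707). Mitochondrial ribosome genes were called without control replicate 2 (adjusted p = 0.0197). None of these calls held with an estimated correlation (lowest adjusted p = 0.741 with an estimated correlation). In the same comparison the mitochondrial ribosome had a median of 0.06, glycolysis 0.08, TCA cycle and fatty acid oxidation 0.03, hypoxia 0.02, p53 targets -0.03, BCL2 family 0.07, mitotic genes 0.00, DNA replication 0.05, DNA damage -0.06 and cytarabine metabolism -0.02. Cytosolic ribosomal proteins had 0.03, the ATF4 response 0.06, the unfolded protein response 0.05, MHC class I presentation -0.04, NF-kB -0.03, fatty acid synthesis 0.02, NRF2 targets 0.05, and lysosome and autophagy 0.02. Monocyte genes had 0.02, granulocyte markers 0.01, the LSC17 stem cell genes -0.01 and KMT2A fusion targets 0.03. The mean differed in sign from the median for fatty acid synthesis (mean -0.02), cytarabine metabolism (0.06), heat shock (0.03), T and NK cell (0.04) and B and plasma cell markers (0.03). With all 9 arrays none of these lists passed in any of the 3 comparisons.

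Changes from control were compared across genes, which are not independent replicates. The changes after AraC and after the combination correlated with r = 0.491 and rho = 0.45, and within the 3 experiments with r = 0.501, 0.466 and 0.446. Both use the same control arrays, and simulated unchanged arms gave r = 0.5 on average, from 0.485 to 0.514. The observed covariance was 0.011, against 0.00906 in the simulation, a difference of 0.00189. Changes taken from different experiments, which share no control array, correlated with a mean r of 0.0127 (from -0.0899 to 0.0764 over 6 pairs). The change after the combination in 1 experiment correlated with that in another at 0.0175 to 0.0352, and after AraC at -0.0251 to 0.00425. All 3 experiments gave the same direction for 24.8% of genes after the combination, 21.9% after AraC and 23.6% for the addition of venetoclax, where chance gives 25%. IDH status was carried by 1 experiment each, so it cannot be told apart from the experiment and was not tested.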

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

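Protein-coding genes only, all probe sets, changes from different experiments, an estimated correlation with arrays left out and the settings for the comparison of experiments were chosen after the data were seen; the other settings were fixed earlier. For single genes, 0 calls held for the addition of venetoclax under every setting run. For AraC against control the count was 2 with array weights or median scaling and 1 without genes of a mean log2 value under 4.496, without those under 5.36, or with quantile normalization, and for the combination against control 1 with median scaling. These calls were MIR3143, MIR32 and MIR601, microRNA loci. Leaving out replicates or arrays gave 0 to 2 genes for AraC, with MIR3143 and MIR32 called without AraC+venetoclax replicate 1. All probe sets, named or not, gave 0 in each comparison, and so did the fit without the block.

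For the combination against control the number of lists called was 1. It was 0 without the replicate block, with no intensity trend, with array weights, without dim genes at either limit, with quantile normalization, with an estimated correlation and with fry, 2 with protein-coding genes only and 3 with only the 6 arrays of the arms compared. The counts of 0 lists for the other comparisons stayed 0 without the block. Across 24 settings the adjusted p of MYC targets ran from 0.0145 to 0.808, under 0.05 in 10. Leaving out replicates or arrays gave 0 to 3 lists here, 0 to 4 for AraC and 0 to 4 for the addition of venetoclax. MYC targets were lost without replicate 1 or 2, without control replicate 1, AraC+venetoclax replicate 1 or 2, or AraC replicate 2 (adjusted p 0.766, 0.0759, 0.718, 0.389, 0.153 and 0.0682). Of 12, 15 and 18 list calls made with 1 left out in the 3 comparisons, 0 held with an estimated correlation. No list passed under that setting with all arrays either, so these losses say little about a single list. An array left out leaves an arm with 2, which are assumed to vary like the others. The cause was not tested. An estimated correlation widens the null of a list whose genes move together. It also raised p for cholesterol synthesis after the combination, where the estimate lay under the preset 0.01.

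The correlation of the changes from control was 0.453 without genes under 5.36, 0.0127 for changes from different experiments, and 0.369 to 0.662 with replicates or arrays left out. The mitochondrial ribosome median for added venetoclax turned from -0.0304 to 0.0675 without AraC replicate 1. Among the lists followed through every case with 1 left out, other medians whose sign turned were those of surface markers after the combination (-0.141 to 0.0212) and mitotic genes for added venetoclax (-0.118 to 0.0349). After AraC they were those of complexes II to V (-0.0154 to 0.118), mitochondrial ribosome (-0.0347 to 0.119) and mitotic genes (-0.0166 to 0.189). Among genes these were BCL2 (-0.0577 to 0.108 after the combination, -0.129 to 0.00142 for added venetoclax), BCL2L1 after AraC (-0.0074 to 0.179) and MCL1 for added venetoclax (-0.0211 to 0.038, and -0.00261 with quantile normalization), all near 0. With all replicates kept, 413 gene results (the count between experiments included) kept their direction and side of the threshold under an alternative, 2 were stronger, 1 weaker and 1 reversed; of list results 169 kept both, 8 were weaker (MYC targets), 3 stronger (cholesterol synthesis and complexes II to V) and 0 reversed. With replicates or arrays left out, 457 gene results kept both, 9 were weaker and 14 reversed, and of list results 133 kept both, 30 were stronger, 11 reversed and 6 weaker. Robust moderation does not apply to camera and was not run for lists. Signal over background is not known per probe set, which limits what can be said of dim genes.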

Other observations

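The tests of precision at 2-fold, of the correlation within MYC targets, of dim probe sets and of handling, and the comparison of experiments itself, were chosen after the result was seen; counts over other splits of the arrays and the recovery of 1.5-fold changes were planned.

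The experiments differed from each other more than the arms did. With the arm as a term, limma's F test called 265 of 14884 genes between the 3 experiments, of which 196 were highest in experiment 3 and 167 lowest in experiment 1. Each experiment is 1 round, so these p-values do not measure how repeated rounds of the same cells would differ. The genes named here were chosen after their values were seen. MIR3143, the microRNA locus closest to a call after AraC, had the smallest p between experiments. Its means were 11.21, 9.44 and 8.62 in experiments 1, 2 and 3 (F test adjusted p = 1.59e-06). RGS1 had a mean log2 value of 6.86 ± 0.25 (SD, n = 3 arrays) in experiment 1, 7.63 ± 0.48 in experiment 2 and 9.48 ± 0.36 in experiment 3 (adjusted p = 4.7e-06). The stress transcription factor ATF3 was 1.57 higher in experiment 3 than in experiment 1 (adjusted p = 0.0012), the lymphoid regulator TOX 1.57, CD86 1.17, the bone marrow homing receptor CXCR4 1.23, the myeloid receptor TREM1 1.73 and NAMPT, an enzyme of NAD synthesis, 1.72. The granule proteases of early myeloid cells, CTSG and PRTN3, differed by -0.84 and -1.08 between experiments 3 and 1, and MNDA by -0.69. Of the 10 genes that lead the comparison of the combination with control, 5 were among the 265 of 14884. RGS1, CD86, CRLF2, CPED1 and KCNRG differed between experiments 3 and 1 by 2.62, 1.17, 1.44, 1.18 and 0.89, more than between arms. Both tests rest on the same residual spread, so a gene with a small spread is favoured in both and part of this overlap is built in.

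Among the lists, NF-kB genes were higher in experiment 3 than in experiment 2 in 19 of 21 members (median 0.25, camera adjusted p = 1.73e-08; adjusted p = 0.0846 with an estimated correlation). DNA replication genes were lower in 24 of 25 members (median -0.18, adjusted p = 7.45e-07; adjusted p = 0.121 with an estimated correlation), and cholesterol synthesis genes were higher in all 17 (median 0.15, adjusted p = 0.00185; adjusted p = 0.144 with an estimated correlation). Lists that respond to handling differed between the same experiments: immediate early genes were higher in 13 of 16 members (median 0.24, adjusted p = 2.11e-05; adjusted p = 0.304 with an estimated correlation) and heat shock genes lower in 7 of 8 (median -0.22, adjusted p = 0.000743; adjusted p = 0.144 with an estimated correlation). Targets of the KMT2A fusion were higher in experiment 3 than in experiment 1 in 11 of 13 members (median 0.34, adjusted p = 4.88e-05; adjusted p = 0.204 with an estimated correlation). IDH status, the cells used, the batch label and the xenograft round change together here and cannot be told apart.

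Chance is argued against for the difference between experiments, though 100 splits cannot exclude it. Of 100 splits of the 9 arrays into 3 sets of 3, 1 called as many genes, the real one. The highest other split called 45. Noise of dim probe sets is argued against, since 5.28% of the 265 genes have a mean log2 value under 4.496 (95% exact interval 2.92% to 8.71%, where chance gives 33.3%). That interval treats the genes as independent, which genes measured on the same arrays are not. A response to handling of the cells stays open, as do the batch and the cells used with their IDH status, which were not tested. Between experiments 3 and 1 immediate early genes had a median of 0.02 and heat shock genes -0.01. Their members went both ways (SD 0.54 and 0.38), with a camera adjusted p = 0.852 with an estimated correlation for immediate early genes. Immediate early genes were also lower in experiment 2 than in experiment 1 (median -0.28, 3 of 16 higher, camera adjusted p = 2.94e-05; adjusted p = 0.594 with an estimated correlation), and higher in experiment 3 than in experiment 2. The count depends on experiment 3, without which 5 genes were called, against 157 without experiment 1 and 173 without experiment 2, and it ran from 79 to 369 when 1 array was left out.

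The absence of called genes between arms was weighed against low precision. For most genes low precision at 2-fold is argued against, since the interval lay within 2-fold for at least 99.4% of genes in each comparison. That share does not show that a 2-fold change would be called. The genes with an estimate over 2-fold (1, 2 and 2 in the 3 comparisons) were microRNA loci and none was called. After AraC MIR4441 differed by 2.07 ± 0.46 (3.16, 1.22 and 1.83 in the 3 experiments, limma adjusted p = 0.999). At 1.5-fold it stays open, since simulated changes of that size were recovered in at most 72.5% of genes. Smaller changes, or changes that differ between the 3 experiments, could exist without a call, and an effect of the drugs of that size stays among the open explanations. Splits of the 6 arrays of 2 arms number 10, too few for a share under 0.05; the real split called 0 genes, which 10 of 10 splits match by construction, and the highest other called 0, 1 and 0 for the combination, AraC and added venetoclax.

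Whether the call of MYC targets after the combination rests on the correlation of its genes cannot be decided here. The adjusted p was 0.808 with that correlation estimated at 0.116 (0.0145 to 0.808 over 24 settings). However, no list passed under that setting in any comparison. For cholesterol synthesis, whose estimated correlation of -0.048 lay under the preset 0.01, the camera p still rose from 0.00385 to 0.0358. The median of MYC targets stayed between 0.05 and 0.13 when replicates or arrays were left out. The 10 splits are too few for a share under 0.05: 7 called at least as many lists as the real 1, the highest other called 3, and the 3 others that also part every pair called at most 1. For AraC and added venetoclax the real count of lists was 0, so 10 of 10 splits match it by construction, and the highest other called 5 and 3, and no split called a list with an estimated correlation. An effect of venetoclax with AraC on MYC targets stays among the open explanations.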
